A study of Homo sapiens with 6 samples.

How the data were processed

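RNA was sequenced from human blood natural killer (NK) cells, isolated as CD56-positive, CD3-negative cells from 3 donors. The cells of each donor were split between a 16-hour incubation in low-dose IL-15 at 1 ng/mL (group LD) and a 16-hour incubation in IL-12 at 10 ng/mL, IL-15 at 50 ng/mL and IL-18 at 50 ng/mL (group CIML). All cells were then washed and kept for 6 days in IL-15 at 1 ng/mL before RNA was taken, so that there were 6 libraries, 3 in each group, with each donor present once in each. Per the labels' protocols, RNA was purified on columns for small amounts and libraries were made by standard Illumina protocols. Whether polyadenylated RNA was selected, whether ribosomal or globin RNA was removed and whether libraries kept strand were not given in the sources used here.

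The authors deposited 1 table of moderated log2 CPM, that is read counts scaled to the library's total and put on a log2 scale after a small count had been added, with 1 column per library. Per the submitters' processing notes, the build was GRCh38 and the tools included bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5 and Salmon 0.8.2, with no role or order stated. The annotation release, the added count and any filter on genes were not given in the sources used here. The table held 34343 rows for 34213 distinct Ensembl gene identifiers, and the 130 repeated rows, which carried identical values, were dropped. In every library the lowest value was the same, −5.11 log2 CPM or 0.0289 CPM. After this floor was subtracted on the linear scale, 100% of the values were whole multiples of 1 step per library within a tolerance of 0.1, so each library's reads could be recovered. The linear values summed to 996657 to 998007 per library, which leaves little room for a further scaling factor between libraries. Recovered depth was 4491237 to 9980484 reads per library. One read was worth 0.0999 CPM in the deepest and 0.222 CPM in the shallowest library, and counts of a few reads carry wide counting error. Gene symbols, types and positions were taken from GENCODE release 29 on GRCh38, which matched 34209 of the 34213 identifiers.

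XIST, TSIX and Y-linked genes, 128 in all, were left out before any test so that nothing bore on a donor's sex. Of the 34085 genes that remained, 22333 were tested, those with a log2 CPM of 0 or more in at least 3 of the 6 libraries. Before the data were examined, the test was set as limma 3.58.1 in R 4.3.3 on the deposited log2 values (linear model with empirical Bayes moderation, mean-variance trend and robust hyperparameters), CIML minus LD, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and without a term for the donor. The same fit with the donor as a replicate block was set beside it as an alternative. The pairing comes from the donor named in the titles of the libraries. Over 3171 genes with a mean log2 CPM of 6 or more, the deviations of same-donor libraries from their group means correlated with Pearson's r of 0.564, 0.552 and 0.568 across genes. The highest r of each CIML library with another donor's LD library was −0.12, 0.12 and −0.28 there. Over all tested genes the same-donor r was 0.155, 0.191 and −0.03, against 0.180, −0.05 and 0.095 with another donor's. Over all tested genes the same-donor r was thus not the highest in donors 1 and 3, and genes are not independent replicates. Fold changes are differences of mean log2 CPM. For genes near the floor they depend on the added count, and libraries with few or 0 reads can make them larger than the ratio of mean CPM. Standard errors in the text are those of the donor-blocked fit.

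Gene lists numbering 30 were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares the members of a list with all other tested genes, so a list it calls higher or lower is so relative to those genes. Camera with an estimated correlation, fry, and each of these with the donor block were run beside it. Members of a list were also counted after adjustment over the list alone. Named genes were fixed by a rule before the data were examined. It takes up to 8 genes of largest change in each direction among those past the threshold without the block, the 4 members of each list with the smallest p in that fit, and 15 genes named in advance (among them IL2RA, KLRC1, NCAM1, FCGR3A, IFNG, GZMB, PRF1, TNFSF10, CISH, GATA3, TBX21, EOMES, CD69 and MKI67). Other genes in the text were chosen after their values were seen, mostly because the donor-blocked fit called them. They are CX3CR1, S1PR1, CXCR1, IL12RB2, MYOM2, ADGRG1, FGFBP2, HBB, PPBP, PF4, GATA1, CAVIN2, MMRN1, HBG2, CD36, ALAS2, ADGRG3, DPP4, ENTPD1, PDE4B, SAMSN1, S100A4, S100A6, PTGDS, SH2D1A, DGKA, PIK3AP1 and MALAT1.

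Alternatives set before the data were examined were the donor block, no filter and a stricter filter of log2 CPM 2, added values of 1 and 5 CPM, centring each library on its median, quantile normalization, no trend, no robust step, array weights, a test against a 1.2-fold change, and leaving out each library and each donor. Alternatives chosen after seeing the data were voom on the recovered reads with and without the block, centring on abundant genes, and the block combined with other settings. A result of a list or gene was taken as reversed only where it passed the threshold before or after the change. Reads of near-identical genes, such as the killer-cell immunoglobulin-like receptor genes, FCGR3A and FCGR3B, HBA1 and HBA2, the HLA genes and KLRC1 to KLRC3, could have been split or dropped in counting, and their values are uncertain.

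The procedure was tested on simulated data for the CIML and LD comparison over 22333 genes. Of 100 genes changed by 1 on the log2 scale, 15% were called without and 27% with the donor block, and of 100 genes changed by 2, 78% and 85%. Of 22115 unchanged genes, 1 was called without and 14 with the block. With the block the unchanged genes made up a larger share of the calls than the threshold of 0.05 aims at. That fit had 2 residual degrees of freedom. A list of 18 genes shifted by 0.5 had an adjusted p of 2.0e-27 with the preset correlation, 0.040 with an estimated one and 0.065 with fry without the block, and 3.7e-43, 0.19 and 0.19 with it. The simulated genes were drawn independently of each other. The list results therefore do not show how the tests behave where members vary together, as in the CD56dim list (estimated correlation 0.30). Nor did the simulation hold a shift of weakly expressed genes between libraries, such as the real ones have, so its gene results do not cover that. Python 3.11.15 with matplotlib 3.10.9 drew the plots.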

Results

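NK cells from 3 donors were compared 6 days after a 16-hour exposure to IL-12, IL-15 and IL-18 (CIML) or to low-dose IL-15 (LD), with 3 libraries per group and both groups kept in the same low dose of IL-15 in between. IL-12 and IL-18 are cytokines that activate NK cells. IL-15, which keeps NK cells alive, also differed in dose during the 16 hours, at 50 ng/mL in CIML and 1 ng/mL in LD. The comparison asks which transcripts still differed after the days in low-dose IL-15. Recovered depth was 4977814, 7271715 and 6252401 reads in CIML of donors 1, 2 and 3, and 8259417, 9980484 and 4491237 reads in LD. The libraries also differed in the level of weakly expressed genes. The median log2 CPM of the tested genes was 3.68, 3.29 and 3.16 in CIML and 3.27, 2.66 and 3.66 in LD, so it was higher in CIML in donors 1 and 2 and lower in donor 3. Summed CPM over 351 olfactory receptor genes, which blood cells hardly use, followed the same order within each donor, with 592, 380 and 415 CPM in CIML and 373, 215 and 657 CPM in LD. The first principal component took 48.3% of the variance and did not separate the groups. On the third, with 13.9%, CIML lay at −31.1 to −23.1 and LD at −14.0 to 69.9.

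**Figure D1:**
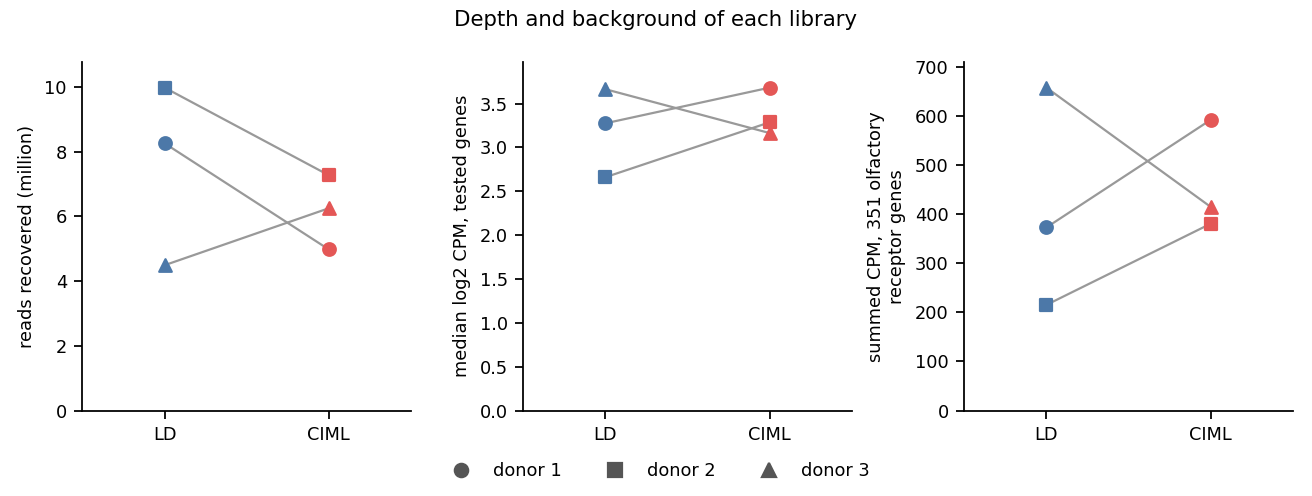
Recovered reads, median log2 CPM of the tested genes and summed CPM of 351 olfactory receptor genes for each library, with LD in blue, CIML in red, 1 marker shape per donor and grey lines joining the libraries of a donor. The median was 3.66 in LD and 3.16 in CIML of donor 3, the reverse of the order in donors 1 and 2.

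After IL-12, IL-15 and IL-18, the cultures held more transcript of the chemokine receptors CXCR6 and CCR1 and of NDFIP2, an adaptor of the NEDD4 family of ubiquitin ligases. FCER1A, the alpha chain of the high-affinity IgE receptor, SLC40A1, the iron exporter ferroportin, and MEF2C, a transcription factor, were lower. Whether the lower genes fell within NK cells or with other cells in the cultures was not told apart. These 6 genes, 3 higher and 3 lower, were the ones past the threshold without the donor block, where 214 genes were higher and 161 lower at an unadjusted p under 0.05. With the donor as a block, 36 genes rose and 36 fell. The 72 included the 6. When each library was also centred on the median of its tested genes, which shifted the median fold of all genes by −0.18 from 0.11 on the log2 scale, the blocked test called 9 higher and 50 lower genes, of which 21 were among the 72. Voom on the recovered reads called 3 higher and 0 lower genes without the block (521 at an unadjusted p under 0.05) and 51 higher and 57 lower with it, of which 70 were among the 72. Centring on abundant genes and adding 1 CPM, each with the block, kept 69 and 70 of the 72. Without donor 3, the blocked test called 1865 higher and 348 lower genes. Camera called 3 lists higher and 6 lower of 30, and 0 with an estimated correlation, while other divisions of the same 6 libraries gave up to 19 list calls. All other gene calls below are those of the donor-blocked test unless stated. Of the called genes, CXCR6, NDFIP2, FCER1A, SLC40A1, MEF2C, CCR7, GZMK, HBD and GATA1 also passed with median centring and the block, while CCR1, CX3CR1, S1PR1, CXCR1, GZMB, GZMA, IL2RA, IL12RB2, IL18R1, CCL5, IL32, MYOM2, ADGRG1, FGFBP2, ZEB2, NCAM1, KLRC1, HBB, KIR2DL4, BIRC3, MT-RNR1 and MT-RNR2 did not. Without donor 1, the blocked calls of CCR7 (adjusted p 0.35), CXCR1 (0.062), IL2RA (0.23), ZEB2 (0.052), BIRC3 (0.32), KIR2DL4 (0.11) and HBB (0.051) were lost. Without donor 2, those of CCR7 (0.94), CXCR1 (0.94), IL2RA (0.084), ZEB2 (1.0), FGFBP2 (0.51), CCL5 (0.14), IL32 (1.0), BIRC3 (0.59), KIR2DL4 (0.12) and MT-RNR2 (0.71) were lost.

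CXCR6 (ENSG00000172215, GRCh38 chromosome 3, 45940933 to 45948353) had 6.76 ± 0.07 log2 CPM in CIML and 4.40 ± 0.64 in LD (mean ± SD, n = 3), a 5.13-fold rise with a log2 fold change of 2.36 (SE 0.21) and a limma adjusted p of 0.0018 without and 2.3e-06 with the block. The CCR1 gene (ENSG00000163823, chromosome 3, 46201709 to 46208396) rose 3.1-fold, from 5.86 ± 0.11 to 7.49 ± 0.17 log2 CPM (adjusted p 5.0e-04 without and 6.1e-07 with the block). Transcripts of NDFIP2 (ENSG00000102471, chromosome 13, 79481124 to 79556075) rose 3.31-fold, from 4.34 ± 0.47 to 6.07 ± 0.27 log2 CPM (adjusted p 0.038 and 1.5e-04). For FCER1A (ENSG00000179639, chromosome 1, 159289714 to 159308224) the log2 CPM was 5.42 ± 0.71 in LD and −0.66 ± 0.50 in CIML, 67.5-fold lower (adjusted p 3.2e-04 and 3.5e-06). The CIML libraries held only 2, 5 and 5 FCER1A reads, against 386, 667 and 113 in LD. SLC40A1 (ENSG00000138449, chromosome 2, 189560579 to 189583758) was 10.6-fold lower, at 2.87 ± 0.34 in CIML and 6.28 ± 0.70 log2 CPM in LD (adjusted p 6.6e-04 and 1.0e-06). Finally, MEF2C (ENSG00000081189, chromosome 5, 88717117 to 88904257) was 3.07-fold lower, at 4.51 ± 0.50 and 6.13 ± 0.17 log2 CPM (adjusted p 0.047 and 2.3e-04). Without the block, NDFIP2 lost its call when any of CIML 1, LD 1, CIML 2 or CIML 3 was left out (adjusted p 0.052, 0.12, 0.32 and 0.31), and MEF2C when CIML 1, LD 1 or CIML 3 was (0.11, 0.23 and 0.20). With the block and libraries centred on their medians, CCR1 had an adjusted p of 0.24.

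Receptors that guide cell migration moved in both directions. Of 24 tested genes of homing and adhesion, 3 rose and 4 fell with the block, against 2 and 0 without it. Adjusted over the list alone, 5 rose and 6 fell with the block and 3 rose and 1 fell without. CXCR6 and CCR1 were among those that rose. By contrast CCR7, which directs cells to lymph nodes, fell 2.63-fold (log2 fold change −1.39, SE 0.28, adjusted p 0.032). CX3CR1, the fractalkine receptor, fell from 9.68 ± 0.66 to 8.90 ± 0.71 log2 CPM (adjusted p 4.2e-04), S1PR1, which guides exit from tissue into blood, fell by 0.88 on the log2 scale (adjusted p 0.0023) and CXCR1 fell by 0.94 (adjusted p 0.049). CD69, an early activation marker, had a log2 fold change of −0.16 (SE 0.11) and did not pass. The list as a whole was not called (camera adjusted p 0.44), and its median of 0.06 became −0.12 under median centring and −0.0074 under quantile normalization.

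**Figure D2:**
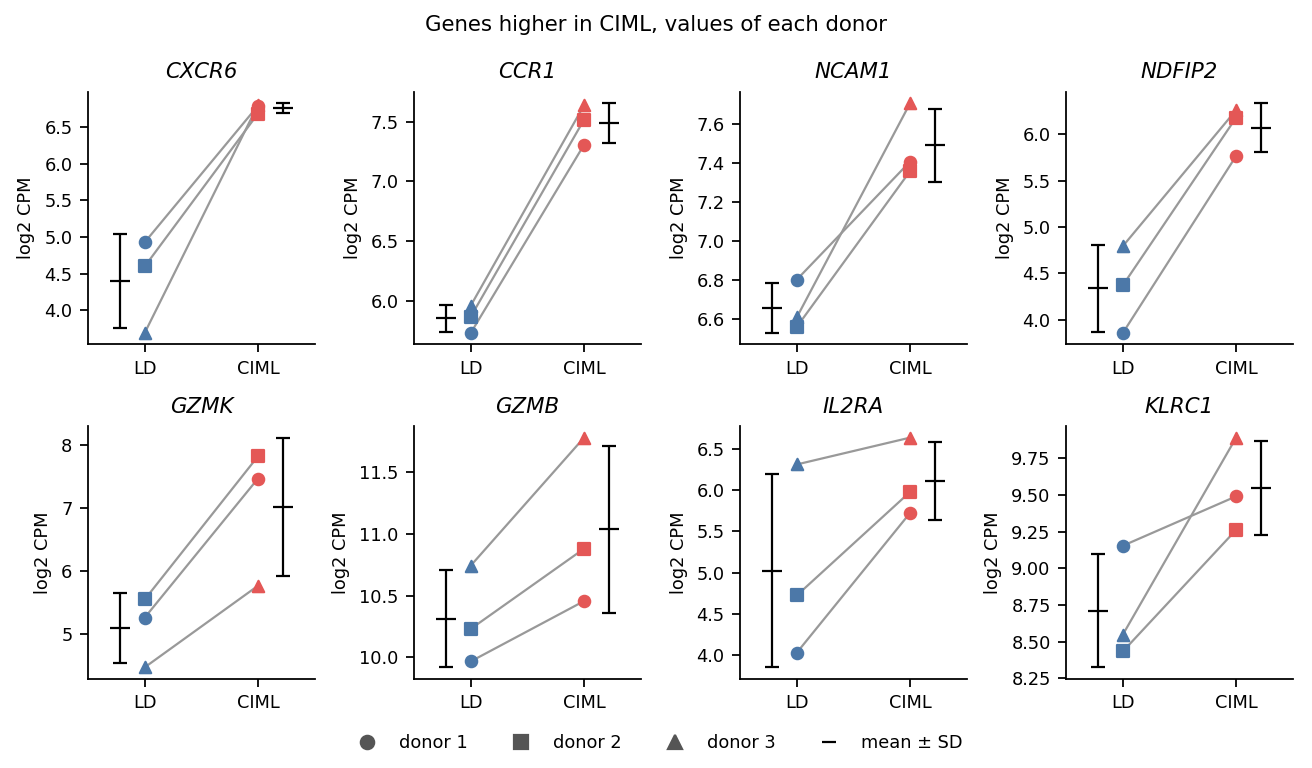
Log2 CPM of 8 genes higher in CIML, with LD in blue, CIML in red, 1 marker shape per donor, grey lines joining the libraries of a donor, and the mean ± SD (n = 3) in black; each axis has its own range and does not start at 0. CXCR6 lay at 6.76 ± 0.07 in CIML and at 4.40 ± 0.64 in LD, and IL2RA was higher in CIML in all 3 donors although the groups overlapped.

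The granzymes GZMK, GZMB and GZMA and the cytokine receptor chains IL2RA, IL12RB2 and IL18R1 rose with the block. Of 18 tested cytotoxic effectors, 3 rose with the block and 0 without, and 6 and 1 rose after being adjusted over the list alone. The 3 were GZMK (3.80-fold, log2 fold change 1.93, SE 0.18, adjusted p 3.4e-06), GZMB (1.65-fold, from 10.31 ± 0.39 to 11.04 ± 0.68 log2 CPM, adjusted p 0.0014) and GZMA (1.71-fold, adjusted p 0.041 with the block and 0.85 by voom with the block). PRF1, which encodes perforin, had a log2 fold change of 0.07 (SE 0.12), and TNFSF10, which encodes TRAIL, 0.56 (SE 0.14, adjusted p 0.13), and neither passed. The list was called higher by camera (adjusted p 5.3e-05), a call lost with an estimated correlation (adjusted p = 0.41). Its median log2 fold change was 0.19 and became 0.01 under median centring, where the list was not called (adjusted p 0.33). Among 22 cytokine receptors 3 rose with the block and 0 without, and adjusted over the list alone 6 rose and 3 fell with the block and 0 did without. IL2RA, the high-affinity IL-2 receptor chain, rose 2.13-fold from 5.02 ± 1.17 to 6.11 ± 0.47 log2 CPM (adjusted p 0.025), IL12RB2, a chain of the IL-12 receptor, rose by 0.95 on the log2 scale (SE 0.13, adjusted p 4.2e-04) and IL18R1, a chain of the IL-18 receptor, by 0.95 (SE 0.16, adjusted p 0.0070).

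Of 18 tested secreted cytokines and chemokines, 2 rose with the block and 0 without, and adjusted over the list alone 4 rose with the block and 0 without. The chemokine CCL5 rose by 0.51 on the log2 scale (SE 0.10, adjusted p 0.035) and IL32 by 0.57 (SE 0.12, adjusted p 0.039). IFNG, which encodes interferon gamma, averaged 5.64 ± 0.52 log2 CPM in CIML and 4.64 ± 0.86 in LD and was higher in all 3 donors, yet it missed the threshold (log2 fold change 1.00, SE 0.22, adjusted p 0.057). With the block it passed by voom (adjusted p 0.046), with 1 CPM added (0.038) and without donor 3 (1.4e-06), and missed under median centring (1.0). The blocked fit without donor 3 called 1865 higher and 348 lower genes in all. The median log2 fold change of all tested genes was 0.34 there, so passing in that fit says little about IFNG itself. Camera called the list higher (adjusted p 0.041), but not with an estimated correlation (adjusted p = 0.77), nor under median centring (0.28), and its median was −0.11 in donor 3 against 0.45 and 0.52 in donors 1 and 2.

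Of 20 tested markers of mature, CD56dim NK cells, 6 fell and 1 rose with the block, against 0 and 0 without, and 12 were lower in all 3 donors. Camera called the list lower (adjusted p 9.3e-09), but not with an estimated correlation (adjusted p = 0.41), nor did fry. Adjusted over the list alone, 10 fell and 1 rose with the block and 1 fell without. MYOM2 fell 2.32-fold (log2 fold change −1.22, SE 0.15, adjusted p 2.3e-04), and ADGRG1, an adhesion receptor that restrains NK effector functions, FGFBP2 and the transcription factor gene ZEB2 fell by 0.90, 0.73 and 0.70 on the log2 scale (adjusted p 0.0011, 0.0094 and 0.019), with CX3CR1 and CXCR1 the remaining ones. GZMB, which belongs to this list too, rose. FCGR3A, which encodes CD16, was at 9.81 ± 0.35 log2 CPM in CIML and 9.79 ± 0.17 in LD (log2 fold change 0.01, SE 0.11). The median of the list was −0.43 and stayed between −0.61 and −0.41 under the other scalings. CD56bright markers, by comparison, moved in both directions. Of 18 tested, 3 rose and 1 fell with the block and 0 without, and adjusted over the list alone 4 rose and 3 fell with the block and 3 rose and 2 fell without. NCAM1, which encodes CD56, rose 1.78-fold from 6.66 ± 0.13 to 7.49 ± 0.19 log2 CPM (adjusted p 0.0026) and KLRC1, which encodes the inhibitory receptor NKG2A, rose 1.78-fold (adjusted p 0.0064), as did GZMK, while CCR7 fell. KIT, the stem cell factor receptor, had a log2 fold change of −0.55 (SE 0.13, adjusted p 0.12).

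**Figure D3:**
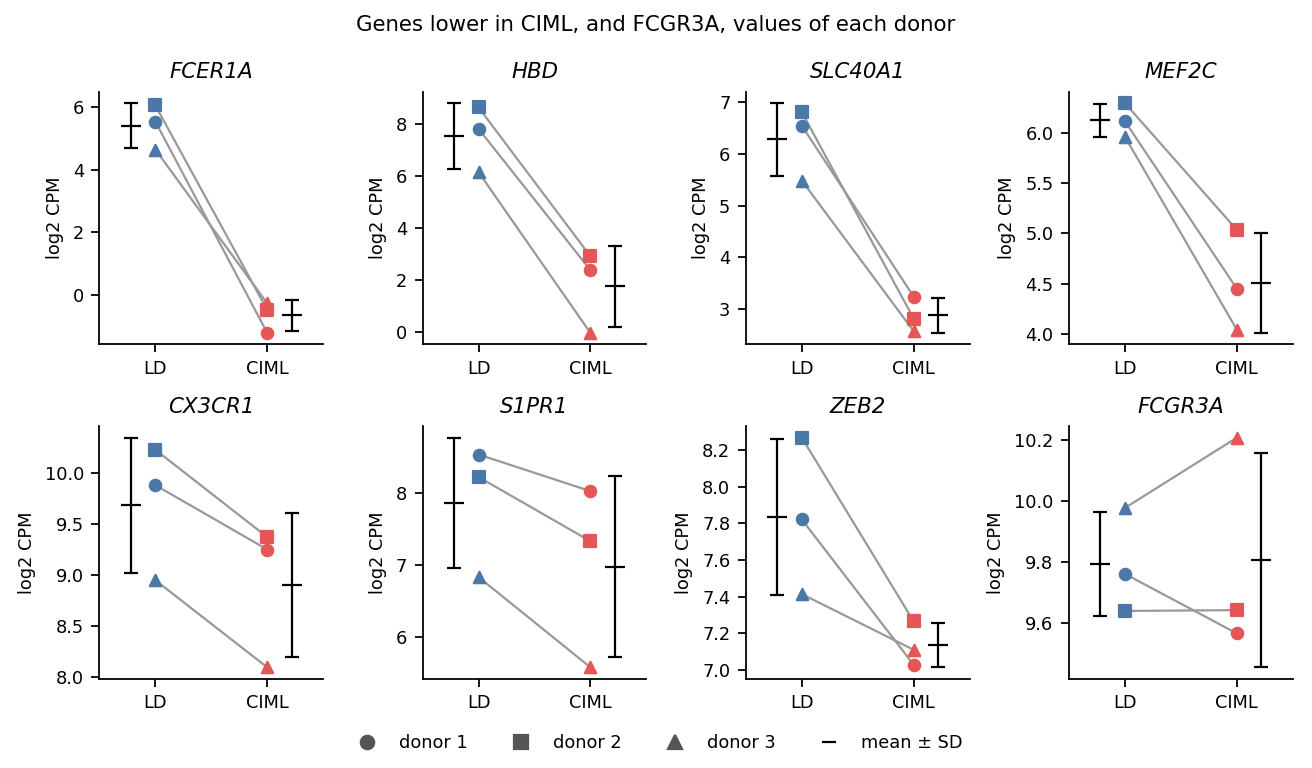
Log2 CPM of 7 genes lower in CIML and of FCGR3A, with LD in blue, CIML in red, 1 marker shape per donor, grey lines joining the libraries of a donor, and the mean ± SD (n = 3) in black; each axis has its own range and does not start at 0. HBD was at 7.53 ± 1.27 in LD and 1.76 ± 1.57 in CIML and fell in all 3 donors, while FCGR3A differed by 0.01 between the means.

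The globin genes HBD and HBB and the transcription factor gene GATA1 fell with the block, although the cells had been isolated as CD56-positive and CD3-negative. HBD, a minor adult beta-like globin, was 54.4-fold lower (log2 fold change −5.77, SE 0.27, adjusted p 5.0e-11), with 26, 55 and 6 reads in CIML and 1858, 3963 and 319 in LD of donors 1, 2 and 3. HBB, the main adult beta globin, was 11.4-fold lower (adjusted p 0.0095) but had 16 and 23 reads in donor 3, and its call was lost under median centring with the block (adjusted p 1.0) and with 1 CPM added (0.14). Both were the members of the 13 tested erythroid and platelet markers that fell with the block, and 0 did without. Adjusted over the list alone, 7 fell with the block and 1 without, and 9 were lower in all 3 donors. PPBP and PF4, abundant in platelets, had log2 fold changes of −3.39 and −2.68 and did not pass (adjusted p 1.0 and 0.057). The list's median was −1.69, and camera called it lower (adjusted p 7.0e-19). With an estimated correlation its adjusted p was 0.054 without and 0.19 with the block, and fry gave 0.23 without and 0.0012 with the block. GATA1, the master transcription factor of red cells and platelets, fell in the same way (log2 fold change −6.14, SE 0.78, adjusted p 2.8e-04), with 1, 6 and 0 reads in CIML and 135, 298 and 18 in LD. FCER1A was the dendritic cell marker that fell, 1 of 14 tested, while the list's median was 0.18 and its call absent (camera adjusted p 0.44). Its direction turned under quantile normalization, to −0.06.

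Markers of other blood cell types held no call over all genes. Of the 18 T cell, 15 B cell and plasma cell, 16 monocyte and macrophage and 13 type 2 and 3 innate lymphoid markers tested, 0 passed with or without the block over all genes. Adjusted over the list alone with the block, 1 T cell marker rose, 2 monocyte markers fell and 1 innate lymphoid marker fell. Camera's adjusted p for these lists was 0.82, 0.58, 0.20 and 0.53. The S100A8 transcript, a monocyte and neutrophil marker, had a log2 fold change of −3.60 (SE 1.15, adjusted p 0.56), and IL1RL1, the IL-33 receptor, 1.23 (SE 0.46, adjusted p 0.98).

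**Figure D4:**
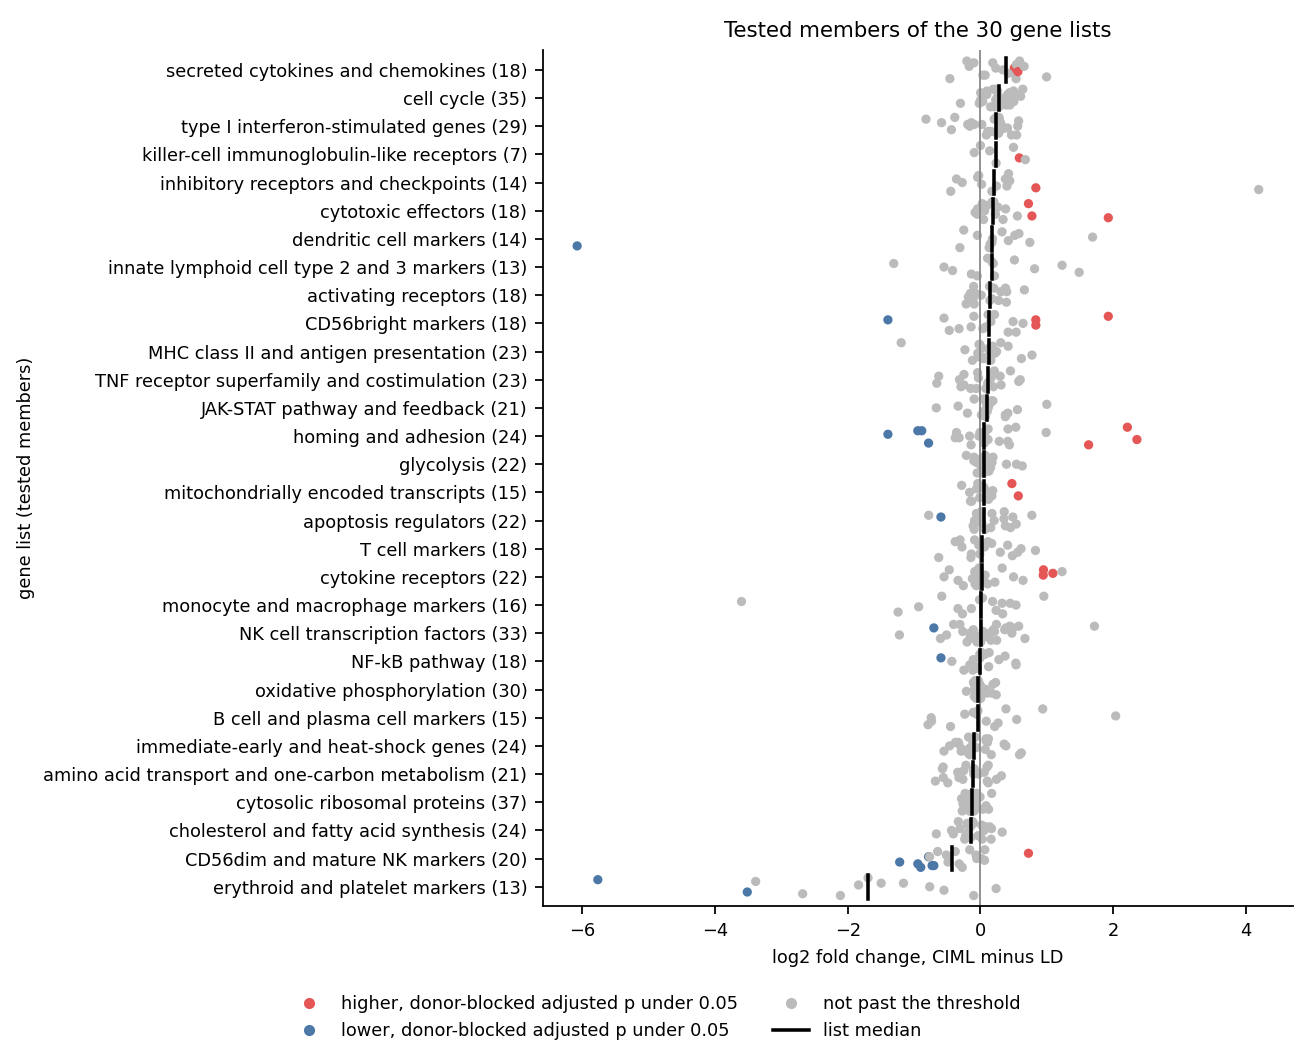
Log2 fold change (CIML minus LD) of each tested member of the 30 gene lists, 1 row per list with its number of tested members, ordered by median. Black bars are list medians and red and blue points are members that rose or fell with the donor block; the erythroid and platelet list has the lowest median, −1.69, and the list of secreted cytokines and chemokines the highest, 0.38.

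Inhibitory and activating receptors held 1 call, KLRC1. It was the 1 of 14 tested inhibitory receptors and checkpoints that rose with the block, with 0 without, and adjusted over the list alone 5 rose and 1 fell with the block and 2 rose without. LAG3, a checkpoint receptor, had 29, 51 and 17 reads in CIML and 12, 4 and 0 in LD and did not pass (adjusted p 0.092). Camera called this list with the block only (adjusted p 0.0029, 0.086 without), and with an estimated correlation and the block its adjusted p = 0.36. Of 18 activating receptors 0 passed over all genes and 4 rose with the block adjusted over the list alone. NCR1, which encodes NKp46, had a log2 fold change of 0.40 (SE 0.12) and was higher in all 3 donors. Among 7 tested killer-cell immunoglobulin-like receptor genes, KIR2DL4 rose by 0.59 on the log2 scale (SE 0.11, adjusted p 0.016), though reads of these genes are hard to assign. The list was called with the block only (camera adjusted p 0.0052, 0.26 without), and with an estimated correlation and the block its adjusted p = 0.55. The medians of the inhibitory and killer-cell immunoglobulin-like receptor lists were 0.21 and 0.24, and they fell to 0.03 and 0.06 under median centring, while the median of the activating receptors went from 0.14 to −0.04.

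Transcription factors of NK cells, JAK-STAT genes and other signalling groups held few calls. ZEB2 was the 1 of 33 transcription factors that fell with the block, and 4 rose and 2 fell adjusted over the list alone. EOMES and TBX21, the T-box factors of NK cells, had log2 fold changes of 0.44 (SE 0.12, adjusted p 0.23) and −0.40 (SE 0.16, adjusted p 1.0), and GATA3 −0.05 (SE 0.18). Of 21 JAK-STAT genes 0 passed, and CISH, a feedback inhibitor of IL-15 signalling, had a log2 fold change of 0.38 (SE 0.21). BIRC3, an inhibitor of apoptosis and a target of NF-kB, fell by 0.59 on the log2 scale (SE 0.12, adjusted p 0.030). It was the 1 call among 22 apoptosis regulators and the 1 among 18 NF-kB genes, and adjusted over the list alone 2 and 1 fell with the block. Over all genes, 0 of 23 TNF receptor superfamily genes, 29 type I interferon-stimulated genes and 23 antigen presentation genes passed. Camera's adjusted p was 0.44 for transcription factors, 0.44 for JAK-STAT, 0.89 for apoptosis, 0.27 for NF-kB, 0.82 for the TNF receptor superfamily, 0.30 for interferon-stimulated genes and 0.44 for antigen presentation.

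Cell cycle, biosynthesis and ribosomal protein lists were called by camera although none of their members passed over all genes, with or without the block. Adjusted over the list alone with the block, 1 cell cycle gene rose and 2 amino acid transport and one-carbon genes fell. The 35 cell cycle genes had a median log2 fold change of 0.28, and 14 were higher in all 3 donors (camera adjusted p 4.7e-05). With an estimated correlation the adjusted p = 0.41, without CIML or LD of donor 3 it was 0.94 or 0.43, and the median was 0.28, 0.0072 and 0.75 in donors 1, 2 and 3. MKI67, the gene of the proliferation marker Ki-67, had a log2 fold change of 0.64 (SE 0.21, adjusted p 0.58). The 37 cytosolic ribosomal protein genes had a median of −0.13, with 18 lower in all 3 donors (camera adjusted p 3.0e-12). With an estimated correlation their adjusted p = 0.41, and RPS6 had a log2 fold change of −0.28 (SE 0.10). Medians of −0.15 for 24 cholesterol and fatty acid synthesis genes, −0.11 for 21 amino acid transport and one-carbon genes and −0.10 for 24 immediate-early and heat-shock genes had camera adjusted p of 5.0e-04, 4.6e-04 and 0.033. With an estimated correlation the adjusted p = 0.56, 0.61 and 0.77. Under median centring the cell cycle median was 0.10 and the list was not called (adjusted p 0.068), nor was the immediate-early and heat-shock list (median −0.27, adjusted p 0.085). The ribosomal protein, cholesterol and amino acid lists stayed called there (adjusted p 0.027, 0.0020 and 0.0023), with medians of −0.31, −0.33 and −0.28. TFRC, the transferrin receptor, had a log2 fold change of −0.57 (SE 0.15, adjusted p 0.24). Glycolysis (22 genes, median 0.06) and oxidative phosphorylation (30 genes, median −0.03) had no call (camera adjusted p 0.70 and 0.20), and the glycolysis median turned to −0.12 under median centring. Of 15 mitochondrially encoded transcripts, the ribosomal RNAs MT-RNR2 and MT-RNR1 rose by 0.47 and 0.57 on the log2 scale with the block (adjusted p 0.010 and 0.023), while the list was not called (camera adjusted p 0.82). Fry without the block called 0 of the 30 lists, and camera with an estimated correlation called 0, with or without the block. The sign of the median differed from the direction of camera's test in lists that were not called. Camera's direction is relative to the other tested genes, and the median log2 fold change of all tested genes was 0.11. The transcription factors, TNF receptor superfamily, apoptosis, T cell, monocyte, dendritic cell, innate lymphoid and mitochondrial lists had medians above 0 and a downward test. Of these, the monocyte and dendritic cell lists had means of −0.25 and −0.13. The innate lymphoid list had a median of 0.17 and a mean of 0.18, both above 0.11, so the median of all genes does not account for its downward test. The B cell and NF-kB lists had medians below 0, a downward test and means of 0.09 and 0.02.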

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

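The combinations of settings with the replicate block, the voom fits and centring on abundant genes were chosen after the data were seen. With the replicate block alone, 36 genes were higher and 36 lower, in place of 3 and 3, and 5 lists were higher, in place of 3, with 6 lower in both. The block changed no other list call in the preset camera test. Of the 72 genes called with the block, 72 kept their direction under median centring and 71 under quantile normalization, MALAT1 being the exception. Median centring moved every fold by the same −0.18, and the smallest of the 72 folds was 0.46 in size, so no direction could turn there. Gene counts (higher and lower) were 23 and 12 without the filter, 5 and 5 with 1 CPM added, 6 higher with 5 CPM added, 0 higher with libraries centred on their medians, and 0 and 0 without the mean-variance trend (444 genes at an unadjusted p under 0.05). The calls without the filter held only 1 of the 6 genes called with it and without the block, and 2 of the 72. Voom without the block called 0 lower. Array weights gave 1808 and 1220, but these did not converge and put nearly all weight on 1 library. With the block, voom called 51 and 57, centring on abundant genes 47 and 37, median centring 9 and 50, 1 CPM added 42 and 37, and no robust step 23 and 22. These held 70, 69, 21, 70 and 44 of the 72 blocked calls, in that order. With the block and without donor 1, 2 or 3, the counts were 38 and 19, 23 and 12, and 1865 and 348, which held 43, 30 and 72 of the 72 blocked calls. Without the block, leaving out a library or donor gave 2 to 13 higher and 2 to 36 lower genes, with the highest counts without donor 3. Apart from fewer libraries, the cause was not tested in any of these cases.

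Lists called higher were 0 with median centring (with and without the block), 6 with quantile normalization, 5 with array weights, 6 by voom with the block, 7 with the block and abundant-gene centring, 8 with the block and 1 CPM added, 5 with the block and no robust step, and 11 and 14 with the block and without donors 1 and 2. An estimated correlation gave 0 higher and 0 lower, with and without the block, and fry gave 0 and 0 without the block and 0 higher and 1 lower with it, the erythroid and platelet list (adjusted p 0.0012). Leaving out a library or donor without the block gave 0 to 14 higher. Some directions turned from those of the fit without the block on all libraries. Under array weights glycolysis was lower (adjusted p 0.0011) and the amino acid and immediate-early lists higher (0.45 and 0.18). With the block, mitochondrial transcripts were higher without donor 1 or 2 (9.5e-04 and 7.2e-09), as they were, short of the threshold, with the block and all donors (0.51), and cell cycle, glycolysis and antigen presentation lower without donor 3 (0.43, 0.0049 and 0.020). Over the leave-outs without the block, adjusted p ran from 2.8e-20 to 0.94 for cell cycle, 1.7e-04 to 0.90 for glycolysis, 5.4e-06 to 0.94 for antigen presentation, 1.2e-07 to 0.94 for immediate-early genes and 1.2e-04 to 0.94 for mitochondrial transcripts, each with both directions among them. The cause was not tested. Among the 6 genes called without the block, the range of log2 fold change over 30 settings was 1.45 to 1.77 for CCR1, 1.80 to 2.62 for CXCR6, 1.49 to 2.26 for NDFIP2, −6.65 to −3.09 for FCER1A, −3.81 to −2.75 for SLC40A1 and −1.88 to −1.35 for MEF2C, and they passed in 27, 26, 19, 27, 27 and 19 settings. Genes that the block alone did not call but voom with the block did included IFNG, TNFSF10, KIT, PF4 and PPBP (adjusted p 0.046, 0.018, 0.049, 2.8e-04 and 0.0025), and those gained by the block with 1 CPM added included IFNG and LAG3 (0.038 and 0.042). At 4491237 to 9980484 reads per library, genes of a few reads could not be compared closely.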

Other observations

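Outside the fixed lists, the donor-blocked test called further genes, named here after their values were seen. Higher in CIML were ADGRG3, an adhesion receptor (3.29-fold, log2 fold change 1.72, SE 0.21, adjusted p 2.0e-04), the surface enzymes DPP4 (3.19-fold, adjusted p 0.0026) and ENTPD1, which breaks down extracellular ATP (2.49-fold, adjusted p 0.0040), and PDE4B, which breaks down cyclic AMP (2.21-fold, adjusted p 3.6e-04). SH2D1A, the adaptor SAP of the SLAM receptors, rose 1.62-fold (adjusted p 0.013), SAMSN1 1.93-fold (8.8e-04), DGKA 1.55-fold (0.036) and PIK3AP1 1.64-fold (0.021). The calcium-binding proteins S100A4 and S100A6 fell 1.58-fold and 1.77-fold (adjusted p 0.0078 and 0.0018) and PTGDS, a prostaglandin D synthase, fell 2.64-fold (0.0040). When libraries were also centred on their medians, ADGRG3, DPP4 and PTGDS passed (adjusted p 0.028, 0.0046 and 0.0027) and the other 8 did not. Without donor 1 the calls of PTGDS, DGKA and PIK3AP1 were lost (adjusted p 0.15, 0.52 and 0.37), and without donor 2 those of DPP4, S100A6, S100A4, PTGDS, DGKA and PIK3AP1 (0.094, 0.070, 0.68, 1.0, 0.73 and 0.12). CAVIN2, MMRN1, HBG2 and CD36, genes of platelets or red cells, fell by 3.45, 2.37, 1.87 and 1.76 on the log2 scale (adjusted p 0.0018, 0.0083, 0.045 and 0.0040). CAVIN2, MMRN1 and HBG2 lost their calls without donor 1 (adjusted p 0.088, 0.36 and 1.0), and all 4 lost them without donor 2 (0.059, 0.94, 1.0 and 1.0 in that order).

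The tests of red cells, of platelets, of depth, of CD56bright cells and of genes of like level described next were chosen after the results they bear on were seen. HBD, HBB, GATA1 and FCER1A, genes of red cells, platelets or basophils, fell with the block, and mature red cells in the LD cultures would bring far more HBB than HBD and more ALAS2 than GATA1. The highest HBB to HBD read ratio in LD was 0.616, and GATA1 exceeded ALAS2 by 4.50-fold to 24.8-fold in LD, which argues against them, although removal of globin RNA, if done, would lower HBB. Platelets in the LD cultures stay open for PPBP and PF4, since PPBP was higher in LD in 2 donors (884 and 2404 reads) and had 0 reads in LD of donor 3, where HBD and FCER1A were still higher. Progenitor cells of the erythroid, megakaryocyte and basophil lineages, more common in the LD cultures, are a candidate explanation that cannot be told apart from a change within NK cells. SLC40A1 lay at 6.55, 6.81 and 5.49 log2 CPM in LD of donors 1, 2 and 3, highest in donor 2 and lowest in donor 3, as HBD and FCER1A were. Whether SLC40A1, MEF2C and other genes lower in CIML come from such cells was not tested. The medians of marker lists written before their values were seen were −0.47 for 13 erythroid, −0.49 for 19 megakaryocyte and −0.55 for 12 basophil and mast cell genes. In donors 1, 2 and 3 they were −0.14, −0.04 and −0.85, then −0.55, −0.89 and −0.53, then −0.68, −0.42 and −0.86. The erythroid median thus came mostly from donor 3. There the median of all tested genes was itself lower in CIML (3.16 against 3.66 log2 CPM), and these lists were not compared with genes of like level. The erythroid and megakaryocyte medians missed the −0.5 the explanation was said to need in each. Of the erythroid, megakaryocyte and basophil members 7, 6 and 4 were lower in all 3 donors, against 7.26% of all tested genes, and 0 of each list were called with the block. Genes already seen to fall with the block, such as GATA1, HBD, HBB, CAVIN2 and MMRN1, were not members. The medians thus leave those genes out, and the 0 calls cannot count against the explanation. For 12 genes of early progenitors the median was −0.35 (−0.15, 0.07 and −0.64 in donors 1, 2 and 3), and isolation by CD56 is expected to remove such cells.

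The libraries differed in the level of weakly expressed genes. Depth as a source of more detected genes is argued against, because the deepest library, LD of donor 2, had a read for 27740 genes, the fewest of all, and the highest count was 28931. Reads spread over the genome, from genomic DNA or unspliced RNA, are consistent with the olfactory receptor genes, whose summed CPM was 2.75-fold higher in the library of highest than in that of lowest median. Which of these sources it may be was not tested, and the order was opposite in donor 3, so that it does not follow the groups. Recovered reads of the olfactory receptor genes ran only from 2153 to 3090 per library. Their summed CPM fell from library to library as depth rose from 4491237 to 9980484 reads. The part of the CPM difference set by depth was not told apart from a difference in such reads.

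Of the 20 CD56dim markers, 12 were lower in CIML in all 3 donors. A larger share of CD56bright cells would lower CD16 with the other markers, and the log2 fold of FCGR3A lay 0.50 above the median of the others, 4.76 of its standard errors but within 2 SDs of the other members' folds (SD 0.46), while NCAM1, KLRC1 and GZMK, markers of CD56bright cells, rose and CCR7 fell, so that such a share cannot be told apart from a change within the cells. Centring on abundant genes, the test first chosen for background reads, moved every fold by 0.0107 alike and decides nothing. Background reads that differ between libraries would move genes of like level alike, but the members' log2 folds less the medians of the 200 genes nearest in mean log2 CPM had a median of −0.50 (quartiles −0.74 and −0.14), against −0.08 to 0.09 in the central 95% of 1000 sets drawn from those genes. The sets were drawn gene by gene, so this band is too narrow for members that vary together (estimated correlation 0.30). The median difference was −0.37, −0.64 and −0.48 in donors 1, 2 and 3, although the order of the background was opposite in donor 3. These values argue against background as the whole cause. A response to IL-12, IL-15 and IL-18, the difference the design names, stays open and was not tested, nor were other changes in the makeup of the cultures.

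The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6 genes without the block, as 1 of the 10 splits did, and the highest of the others called 0, including the 3 others that part each donor's libraries. For lists called by camera with the preset correlation the real split gave 9 and the highest of the others 19, and 9 of the 10 splits gave as many as the real one, so such calls arose in these libraries whichever way they were divided. With the donor block, exchanging the labels within donor 1 or within donor 2 called 0 genes. Exchanging them within donor 3 called 2524 genes, against 72 for the real labels. That division puts CIML of donors 1 and 2 with LD of donor 3, in each donor the library with the higher median of weakly expressed genes and the lower depth, and so points to a structure of the samples that is not the treatment. Without donor 3 the blocked test called 1865 higher and 348 lower genes, and whether the same structure accounts for them was not tested.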
